A study of Mus musculus with 9 samples.

How the data were processed

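Single-cell 3′ RNA libraries of inner ear organoids from the mouse embryonic stem cell line R1/E were analysed from the deposited matrices, 1 for each of 9 conditions. The authors deposited raw UMI counts per gene and barcode, with no normalisation, and the matrices hold 32285 genes. Per the labels' protocols, organoids were dissociated with an enzyme, strained to single cells and loaded on a droplet system. Per the submitters' processing notes, reads were processed with bcl2fastq and Cell Ranger 3.1.0 against the mm10 build, with Seurat 2.3.1 and R 3.5.1 named beside them. The matrix headers name Cell Ranger 4.0.0, so which version made the deposited counts is not settled. The annotation release is not given in the sources used here, and coordinates come from GENCODE M21 of the same build, matched by Ensembl identifier. Whether the matrices were filtered for empty droplets beyond the barcode caller is not given in the sources used here.

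Groups and doses were taken from the labels. The library titled day 10 has day 4 in its characteristics, and was compared with days 8 and 4 by its title only. The 1.5 µM library has day 8 in title and characteristics and day 5 in its deposited names, and was used as day 8. Each group was 1 library, and nothing in the labels gives a batch, so no model was fitted and no p-value was computed. The filters, lists, size rule, thinning, clustering settings and alternatives were chosen before the data were examined, except where said otherwise.

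Barcodes were kept with at least 1000 genes and at most 10% mitochondrial counts, which 58.6 to 74.3% of barcodes met. Doublets were scored with Scrublet as run in scanpy 1.11.5, and the top-scored barcodes were left out at a rate of 0.8% per 1000 barcodes, 11.4 to 14.8% of those passing. Scrublet's own threshold marked 4.38 to 11.5%. Counts of kept cells were summed per library (90920967 to 166392444 UMIs) and divided by the library sum to give CPM. Sums of this depth make counting error small for genes at 10 CPM or more, and give no estimate of the spread between cultures. Free RNA was not corrected for.

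For each comparison, genes with at least 10 CPM in the higher library and a fold of at least 2 were counted each way. A count below 3 was set to a floor of 3 counts, and the fold is then a lower bound. Intervals of a fold are exact intervals for the ratio of 2 Poisson counts, and those of a share are exact Clopper-Pearson intervals, at 95%. There were 33 fixed gene lists, and a list's median log2 ratio was taken over members at 10 CPM or more in either library. Its percentile came from 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries. Only lists with at least 3 measured members have a percentile. Lists share some genes, such as Six3, Hesx1 and Pax6 in both the rostral and the anterior placode list. The step was checked on data simulated for 3 against 0 µM on day 8 over the 7701 genes that met the CPM minimum: 50 of 50 genes drawn at each of 2.5, 4 and 8-fold passed, 0 of 50 at 1.5-fold did, 1 of which lay below the minimum, and 0 of 7502 unchanged genes did. The simulation held counting error only, so it checks the arithmetic of the rule and gives no rate of false calls between cultures.

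Genes were named by a fixed rule. It takes Axin2, Lef1, Sp5, Otx2, Hoxb1, Gbx2, Pax2, Pax8 and Foxi3 in every comparison, though not every value is given here. Some genes that the rule takes are not reported here. Further named were the 2 members with the largest absolute log2 ratio, at 10 CPM or more, of the rostral, Hox 1 to 4, other caudal, Wnt target, pan-placodal, otic, anterior placode, surface ectoderm, neural and neural crest lists. The 5 genes with the largest fold each way at 50 CPM or more were added, leaving out mitochondrial, ribosomal protein and predicted genes. Any list was allowed to be named by its count and median, and its members past the rule are given by name. Other genes named here, such as Hox genes by day and cluster marker genes, were chosen after their values were seen.

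For shares of cells with a UMI, each kept cell was thinned without replacement to 3000 UMIs, and shallower cells were left out. For list shares, at least 3 different list genes had to be seen. The background is the share in pluripotent-like cells for Hox, Pax and neuron genes and in epidermis-like cells for Otx2.

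Clusters were made from 2000 kept cells per library with counts log-normalised. The 2000 variable genes left out mitochondrial and ribosomal protein genes and the axial, Wnt target and cell cycle lists. Then came 30 principal components, 20 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, leidenalg 0.10.2), with no batch integration. The other cells were placed by 15 nearest neighbours. A cluster took a cell type name when at least 3 of the fixed markers, and at least 40% of that list, stood at 3-fold or more over the other cells and at 20 CPM or more. These naming thresholds were set after the clusters were seen, and 11 of 14 named clusters had no more markers of another type than of their own among their top 10 genes and were compared as classes. Within a class, list medians needed 100 cells in each library.

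Alternatives were no filter, a stricter filter (2000 genes, 5% mitochondrial), no doublet removal, median-of-ratios scaling, a mean over cells with every cell weighing alike, other fold and CPM minimums, other thinning depths and list numbers, and other clustering settings. Taking list members at 1 CPM or more was added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.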

Results

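Inner ear organoids were grown from R1/E cells, a line of mouse embryonic stem cells, and were profiled by droplet-based single-cell RNA sequencing. In this assay each captured messenger RNA carries a unique molecular identifier (UMI), and each barcode stands for 1 droplet. All 9 libraries came from cultures with 4 µM IWP2, an inhibitor of Porcupine that blocks the secretion of Wnt ligands. CHIR, the usual short name of a GSK3 inhibitor that activates Wnt/β-catenin signalling inside the cell, was given at 3 µM in 6 libraries, at 1.5 µM in 1 library and was left out of 2 libraries. The series asks how the level of Wnt activation bears on the position of cells along the head-to-tail axis and on inner ear differentiation. The 3 µM libraries were of days 4, 5, 6, 7 and 8, with a further library titled day 10, and the 0 µM libraries were of days 5 and 8. The characteristics of the library titled day 10 give day 4, so it is called by its title throughout. The 1.5 µM library was of day 8 by its title and characteristics, while its deposited names carry day 5.

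Each condition was 1 library, so there were no replicates, no test across samples was made, and batch and condition cannot be told apart. Intervals are exact 95% intervals and cover counting error only. The libraries held 14239 to 18482 barcodes and 121512122 to 216431543 UMIs, the fewest UMIs on day 4 and the most at 1.5 µM. After filtering, 8527 cells remained on day 4 and 9858, 9630, 9393 and 9259 on days 5, 6, 7 and 8 at 3 µM. At 0 µM, 7398 cells remained on day 5 and 9897 on day 8, and 9045 remained at 1.5 µM and 11701 in the library titled day 10. The median UMI count per kept cell was lowest on day 4 at 3 µM (10003) and highest on day 5 at 0 µM (18809), and on day 8 it was 14115, 15819 and 14671 at 3, 1.5 and 0 µM. On day 8 the median mitochondrial share per kept cell was 3.02, 2.81 and 1.33% at 3, 1.5 and 0 µM.

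Genes that the naming rule takes in every comparison stand for Wnt signalling (Axin2, Lef1, Sp5), for axial position (Otx2, Gbx2, Hoxb1) and for placode and otic fate (Foxi3, Pax2, Pax8). Not every one of their values is given. In the GENCODE M21 annotation of the mm10 build, Axin2 (ENSMUSG00000000142) lies on chromosome 11 from 108920349 to 108950783, and Lef1 (ENSMUSG00000027985) on chromosome 3 from 131110471 to 131224356. Sp5 (ENSMUSG00000075304) lies on chromosome 2 from 70474923 to 70477729. Otx2 (ENSMUSG00000021848) lies on chromosome 14 from 48657677 to 48673819 and Gbx2 (ENSMUSG00000034486) on chromosome 1 from 89927956 to 89931179. Hoxb1 (ENSMUSG00000018973) lies on chromosome 11 from 96365752 to 96368256. Foxi3 (ENSMUSG00000055874) lies on chromosome 6 from 70956531 to 70961066, Pax2 (ENSMUSG00000004231) on chromosome 19 from 44756045 to 44837871 and Pax8 (ENSMUSG00000026976) on chromosome 2 from 24420560 to 24475599. Gene values are counts summed over the kept cells of a library, given as CPM, the count of a gene scaled to the total of its library.

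The comparison of 3 with 0 µM CHIR on day 8 asked what the highest dose was accompanied by. Genes of the forebrain and anterior head were lower at 3 µM, and most neuron markers and 5 of 9 direct Wnt target genes were at least 2-fold higher. Six3, a forebrain and eye-field regulator, stood at 0.124 CPM against 24.6 CPM, 199-fold lower (interval 126 to 335), and Lhx2 was 15.1-fold lower. Otx2, which marks forebrain and midbrain, stood at 22.1 against 65.8 CPM, 2.97-fold lower (2.86 to 3.09). Axin2, a negative feedback target of Wnt/β-catenin signalling, stood at 21.8 against 4.60 CPM, 4.73-fold higher (4.37 to 5.13), and Sp5, another direct target, was 24.0-fold higher (18.8 to 31.1).

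By list, all 4 measured rostral genes were at least 2-fold lower, with a median log2 ratio of −3.77 (−4.57 when every cell weighed alike), at percentile 0 of 10000 random lists matched on expression. Of 9 measured Wnt targets, 5 (Axin2, Nkd1, Znrf3, Tnfrsf19 and Sp8) were at least 2-fold higher and none lower, with a median of 1.11 at percentile 100, and Lef1 was 1.65-fold higher (1.57 to 1.74). All 3 measured midbrain-hindbrain genes (Fgf8, Irx2, Irx3) were higher, with a median of 1.82, and so were Egr2 and Fst among 3 further caudal genes (median 1.34). Only 1 of the Hox genes of groups 1 to 4 reached 10 CPM: Hoxb2, a hindbrain gene, stood at 19.6 against 1.48 CPM, 13.2-fold higher (11.6 to 15.1). Below that level, Hoxb1 was 25.6-fold higher at 3 µM. Of the 4 measured Hox genes of groups 5 to 13, which pattern the trunk, 1 (Hoxa7) was at least 2-fold higher, and their median was 0.57, or 1.42 when every cell weighed alike and 1.35 when members at 1 CPM or more were counted.

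The neuron markers were higher in 7 of 8 cases (median 1.90, percentile 100, or 1.16 when every cell weighed alike), among them Neurod1 at 96.9 against 6.12 CPM. Of 5 measured pan-placodal genes, Eya2 (28.5 against 1.96 CPM, 14.5-fold, 12.96 to 16.3) and Irx5 (5.00-fold) were higher, with a median of 0.99. All 7 measured mesenchyme markers were lower (median −1.55, percentile 0), and so were the 3 measured anterior placode genes Six3, Pitx1 and Dlx2, Pitx1 by 87.8-fold. Six3 also counts among the rostral genes. The anterior placode median was −6.46, or −3.62 over the 10 members at 1 CPM or more, −5.40 with no cell filter and −5.36 without doublet removal. The otic markers had a median of −0.68 over 3 measured members, none past 2-fold, which was 0.03 when members at 1 CPM or more were counted. Pax2 (4.26-fold, 3.17 to 5.81) and Pax8 (3.02-fold, 2.66 to 3.43), both otic regulators, were higher at levels of 1.47 and 6.08 CPM, Gbx2 stood at 1.49 and 1.46 CPM, and Foxi3 had 24 and 28 counts. Neural markers had a median of −0.63, or −1.76 when every cell weighed alike, with Hes5 and Fabp7 lower by 2.18-fold and 5.07-fold. Of 8 surface ectoderm markers, Wnt6 was 2.94-fold higher and Dlx5 2.23-fold lower.

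The largest folds among genes at 50 CPM or more were Tlx2 (25.5-fold, 23.2 to 28.0), Sst, which encodes the neuropeptide somatostatin (428 against 19.4 CPM, 22.0-fold), Neurod1 (15.8-fold), Cxcl14 (9.60-fold) and Nefm, a neurofilament gene (7.68-fold). The lowest were Barx1 (147-fold lower, 120 to 183), Dlk1 (9.45-fold), Dnmt3l (4.43-fold), Prrx2 (4.00-fold) and Rasgrp2 (3.995-fold). Of 8005 genes at 10 CPM or more in either library, 188 were at least 2-fold higher and 184 at least 2-fold lower. Part of the stress and immediate early list moved with the same contrast, with 4 of 10 higher at 3 µM (Fosb, Junb, Egr1, Atf3, list median 0.72). So did part of the hypoxia and glycolysis list (Vegfa, Ldha and Bnip3 of 10 higher, list median 0.70). The S phase and G2/M phase lists had medians of −0.56 and −0.69, with 1 of 15 G2/M genes (Cdc20) past 2-fold. The split was 171 higher and 230 lower when every cell weighed alike. Under median-of-ratios scaling it was 230 higher and 130 lower, and the median over all genes was −0.06 in place of −0.19, against which list medians are to be read.

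**Figure D1:**
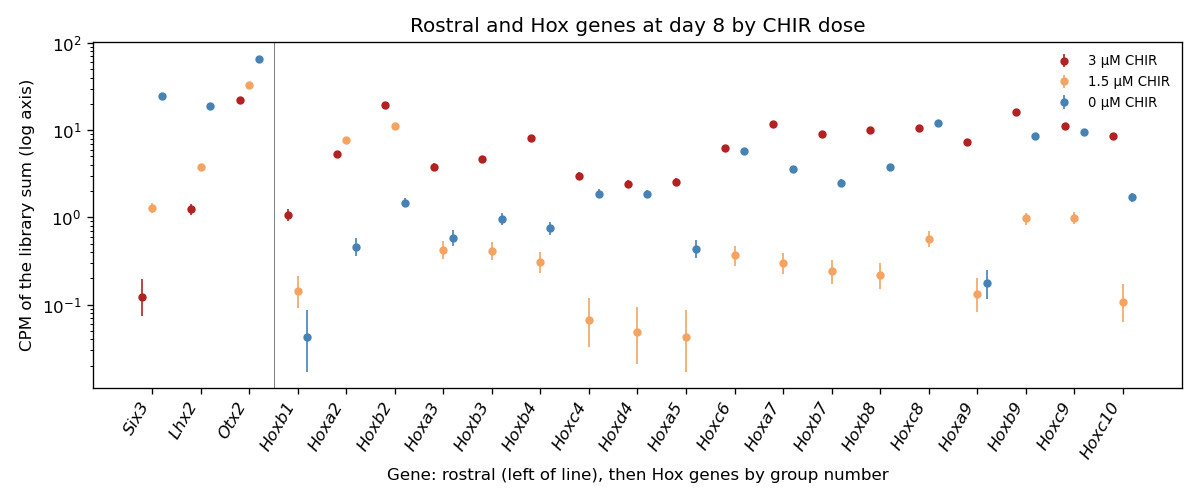
CPM of the library sum (log axis) for 3 rostral genes and for Hox genes ordered by group number on day 8, with 1 point per library at 3, 1.5 and 0 µM CHIR and bars for the exact 95% counting interval. Six3, Lhx2 and Otx2 lie lowest at 3 µM, Hoxb2 lies at 19.6, 11.1 and 1.48 CPM, and Hoxa7 lies at 11.9, 0.300 and 3.59 CPM at 3, 1.5 and 0 µM.

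Shares of cells with a UMI of these genes were compared after every cell was thinned to 3000 UMIs, which left out 268, 173 and 473 shallower cells at 3, 1.5 and 0 µM on day 8. Otx2 was seen in 5.06% of cells at 3 µM (4.62 to 5.53), 7.47% at 1.5 µM (6.93 to 8.04) and 14.9% at 0 µM (14.2 to 15.7), and without thinning in 17.0, 25.1 and 34.8%. A Hox gene of groups 1 to 4 was seen in 14.4% (13.7 to 15.2), 6.199% (5.71 to 6.72) and 2.14% (1.86 to 2.46), and without thinning in 34.5, 18.6 and 6.33%. A Hox gene of groups 5 to 13 was seen in 19.4% at 3 µM, 0.676% at 1.5 µM and 5.93% at 0 µM (34.5, 2.06 and 10.5% unthinned), so these trunk genes did not follow the order of the doses. Cells with both Otx2 and a Hox gene of groups 1 to 4 made up 0.245, 0.214 and 0.0212%, and without thinning 2.87, 3.54 and 0.839%, so no order of 3 and 1.5 µM is read from them.

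As a background level, the pluripotent-like cells, which should lack Hox transcripts, showed a Hox gene of groups 1 to 4 in 1.64, 1.06 and 0.372% and one of groups 5 to 13 in 2.62, 0.796 and 0.372% at 3, 1.5 and 0 µM. Their median depth was 23041, 26352 and 17454 UMIs, against 13898, 15669 and 15168 in the other cells. The share for groups 5 to 13 at 1.5 µM was thus not set apart from this background, which was 3 of 377 cells (0.164 to 2.31). In epidermis-like cells of that library the share was 0.308% (0.0078 to 1.70), not set apart either. It was lower in neural-like cells (0.120%, 0.0146 to 0.434) and in neuron-like cells (0.140%, 0.0289 to 0.409). For Otx2 the background in epidermis-like cells was 0.674, 1.54 and 0.571%, at median depths of 11152, 14031 and 13214 UMIs against 16211, 16159 and 15298 in the other cells. Otx2 was also seen in 17.9, 19.4 and 23.4% of pluripotent-like cells and in 0.604, 4.75 and 40.9% of neural-like cells, so its share over all cells is not one of forebrain or midbrain cells alone. Pax8 was seen in 1.72% of cells at 3 µM, 5.28% at 1.5 µM and 0.594% at 0 µM, and Pax2 in 0.311, 0.271 and 0.106%, with neither seen in pluripotent-like cells. Without thinning the shares were 5.81, 16.4 and 2.20% for Pax8 and 0.918, 0.774 and 0.414% for Pax2. At least 3 neuron markers were seen in 14.8% of cells (14.1 to 15.6), 22.9% (22.0 to 23.8) and 4.29% (3.89 to 4.72), against 0.164, 0.530 and 0% of pluripotent-like cells, and without thinning in 22.6, 35.8 and 7.31% of all cells. At least 3 otic markers were seen in 1.07% (0.866 to 1.30), 1.78% (1.52 to 2.08) and 0.531% (0.394 to 0.699) of all cells. In pluripotent-like cells the share was 0% at each dose, and in epidermis-like cells 0.0792, 1.54 (0.501 to 3.55) and 0%. At 1.5 µM it was 0.0601% in neural-like and 0.0935% in neuron-like cells. The share over all cells at 1.5 µM is thus not set apart from that in epidermis-like cells, but lies above that in the other classes named here. Without thinning the otic shares were 8.91, 19.5 and 10.8%, and with 2 markers 4.78, 9.67 and 5.09%, so no order of 3 against 0 µM is read from them.

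Clustering gave 24 clusters, built without the axial and Wnt target genes, and 14 carried a cell type name from the fixed markers. On day 8 neuron-like cells made up 17.96% of cells at 3 µM (17.2 to 18.8), 24.1% at 1.5 µM (23.2 to 25.0) and 0.829% at 0 µM (0.659 to 1.03). The last share was 5.41% without doublet removal and 1.69% with another draw of cells. At least 3 neuron markers were also seen in 9.05, 13.8 and 18.2% of thinned neural-like cells at 3, 1.5 and 0 µM. At 0 µM these were 318 of the 404 cells with such markers in the library. The neuron-like share at 0 µM thus leaves out most cells with neuron markers. Mesenchyme-like cells were most frequent at 0 µM, at 3.05% (2.71 to 3.42), 5.36% (4.91 to 5.85) and 19.5% (18.7 to 20.3). Epidermis-like cells made up 27.5% at 3 µM (26.6 to 28.4), 3.66% at 1.5 µM and 1.80% at 0 µM, and the shares at 3 and 0 µM depended on the clustering (3.52% at 3 µM without doublet removal, and 33.4% at 0 µM at Leiden resolution 0.5). Neural-like cells made up 5.43, 18.5 and 18.3%, in cluster 8 mainly at 3 µM (5.03%) and 1.5 µM (15.3%) and in cluster 19 mainly at 0 µM (17.7%). With another draw of cells the neural-like share at 3 µM was 0.605%, and without doublet removal that at 0 µM was 0.581%. Otic-like cells made up 3.41% at 3 µM (3.05 to 3.80), 0.0442% at 1.5 µM and 0.0202% at 0 µM. The unnamed cluster 0, led by genes that include Foxi2 and Pax8, held 14.0% at 3 µM (13.3 to 14.7), 27.9% at 1.5 µM (26.9 to 28.8) and 1.33% at 0 µM (1.12 to 1.58). The unnamed cluster 9, with the epidermis markers Trp63, Krt15 and Perp, held 0.454% at 3 µM, 1.48% at 1.5 µM and 34.8% at 0 µM (33.8 to 35.7), and 92.8% of its cells came from that 0 µM library, so it may be that library rather than a cell type. Both fell short of a name by a threshold that was set after the clusters were seen.

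**Figure D2:**
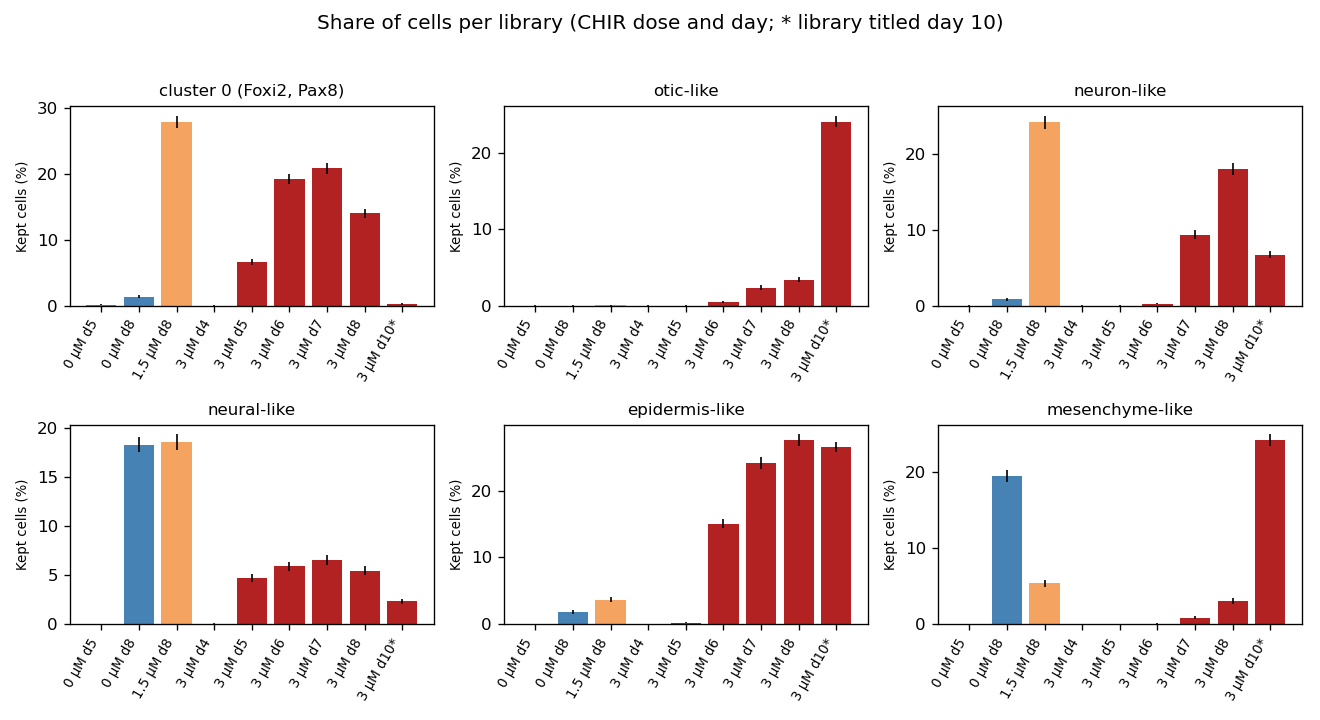
Share of kept cells (%) per library in cluster 0 and in the otic-like, neuron-like, neural-like, epidermis-like and mesenchyme-like classes, with 1 bar per library by CHIR dose (0, 1.5 and 3 µM) and day, and lines for the exact 95% interval. On day 8 the neuron-like share lies at 17.96, 24.1 and 0.829% and the mesenchyme-like share at 3.05, 5.36 and 19.5% at 3, 1.5 and 0 µM, and otic-like cells lie at 24.1% in the library titled day 10.

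The same contrasts were then taken inside 1 class of cells. In neural-like cells (503 at 3 µM, 1811 at 0 µM), 7 of 8 rostral genes were at least 2-fold lower at 3 µM (median log2 −7.08), all 10 measured Hox genes of groups 1 to 4 were higher (median 6.59), and so were all 14 of groups 5 to 13 (median 6.55). At 1.5 µM (1677 neural-like cells), 6 of 9 rostral genes were lower and 2 higher than at 0 µM (median −2.50), and both measured Hox genes of groups 1 to 4 were higher (median 6.26). The Wnt targets in neural-like cells had a median of 1.45 at 3 against 0 µM and 0.86 at 1.5 against 0 µM. Different clusters held most neural-like cells at 0 µM (cluster 19) and at the other doses (cluster 8). The medians within a class were not compared under another draw of cells or without doublet removal. In epidermis-like cells (2547 at 3 µM, 178 at 0 µM), 8 of 10 Wnt targets were higher (median 2.94), as were all 7 Hox genes of groups 5 to 13 (median 4.74). Cluster 2 held most of these cells at 3 µM (24.4% of the library) and cluster 23 at 0 µM (1.79%) and 1.5 µM (3.27%). In mesenchyme-like cells (282 at 3 µM, 1929 at 0 µM), Wnt targets had a median of 2.82, while the Hox genes of groups 5 to 13 went both ways, with 3 higher and 1 lower of 10 (median 0.15, or 1.17 with the axial genes left in the clustering). In pluripotent-like cells (610 and 272) the Wnt targets had a median of −0.10, with 2 of 6 higher.

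The comparison of 1.5 with 0 µM CHIR on day 8 asked what the lower dose was accompanied by. At 1.5 µM, 9 of 10 neuron markers and 4 of 5 pan-placodal genes were at least 2-fold higher, 4 of 5 rostral genes were lower, and of the 6 Wnt targets at 10 CPM or more 1, Axin2, was past 2-fold. The neuron marker median log2 was 2.74 (percentile 100), or 2.11 when every cell weighed alike. The higher pan-placodal genes included Eya1, Eya2 and Irx5 (list median 1.59, percentile 100), with Eya2 at 43.5 against 1.96 CPM (22.1-fold). Pax8 stood at 16.2 against 2.02 CPM, 8.03-fold higher (7.17 to 9.03), and Foxi2, a forkhead gene of the otic list, was 4.46-fold higher. Both were among the leading genes of the unnamed cluster 0, and neither was among the markers that named the otic-like cluster.

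Of 5 rostral genes, 4 were lower (median −1.79, percentile 0), with Six3 19.0-fold, Lhx2 4.88-fold and Otx2 2.02-fold lower (1.95 to 2.08). The 3 midbrain-hindbrain genes were higher (median 1.82), and Hoxb2 was 7.49-fold higher. Axin2 was 2.82-fold higher (2.59 to 3.06), Sp5 3.94-fold higher at 1.62 CPM and Lef1 1.82-fold lower, and the Wnt target median was −0.20 over 6 members, or 0.27 over members at 1 CPM or more. Gbx2 was 2.04-fold, Pax2 1.90-fold and Foxi3 2.74-fold (1.75 to 4.38) higher, at levels under 3 CPM. The otic list had 2 members higher (Pax8, Foxi2) and 1 lower (Tbx2), with a median of 0.60 that was −0.15 when every cell weighed alike. Mesenchyme markers were lower in 4 of 7 cases (median −1.04), anterior placode genes in 3 of 4 (median −1.77, or −2.41 when every cell weighed alike, Pitx1 3.97-fold), and surface ectoderm markers in 3 of 7 (median −0.63, Dlx5 3.85-fold and Msx2 2.36-fold). Neural markers had a median of 0.36, or −0.35 when every cell weighed alike, with Fabp7 3.21-fold higher. Pax3, a member of the neural crest list, was 60.02-fold higher (43.0 to 86.4). That list had a median of 0.28, or −0.14 over members at 1 CPM or more, and Pax3 was also a leading gene of the neural-like cluster 8.

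Outside the lists, among the largest folds were Rgs4 (47.8-fold), Tlx2 (36.2-fold), Nhlh2 (26.3-fold) and Sst (23.7-fold). The lowest were Barx1 (7.54-fold lower), Dlk1 (6.03-fold), Wnt4 (3.62-fold), Dnmt3b (16.6 against 51.7 CPM) and Krt19 (2.81-fold). Of 8135 genes, 251 were at least 2-fold higher and 139 at least 2-fold lower. Stress genes had a median of 0.13 with none past 2-fold.

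The comparison of 3 with 1.5 µM CHIR on day 8 asked what the upper dose step added. Trunk Hox genes were higher at 3 µM, as were 3 of 9 Wnt targets, and 4 of 6 neural markers were lower. All 4 measured Hox genes of groups 5 to 13 (Hoxa7, Hoxc8, Hoxb9, Hoxc9) were higher, with a median log2 of 4.15 (percentile 99.99), or 5.07 when every cell weighed alike and 5.26 over members at 1 CPM or more. Of 9 Wnt targets, 3 (Lef1, Tnfrsf19, Sp8) were at least 2-fold higher (median 0.75, percentile 100), with Sp5 6.10-fold (5.35 to 6.97), Lef1 3.01-fold (2.83 to 3.21) and Axin2 1.68-fold higher (1.59 to 1.78).

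Of 8 surface ectoderm markers, 3 were higher (Gata2 by 3.78-fold, Gata3 and Wnt6 by 3.74-fold), with a median of 0.77, and of 4 epidermis markers 2 (Krt5, Perp) were higher, with a median of 1.27. Of 6 neural markers, 4 (Sox21, Hes5, Fabp7, Pax6) were lower (median −1.16, percentile 0), with Fabp7 16.3-fold (15.2 to 17.5) and Pax6 4.05-fold lower. Neuron markers had a median of −0.63, with 1 of 10 (Neurog2) past 2-fold. Pan-placodal genes had a median of −0.57 with none of 5 past 2-fold, and Pax8 was 2.66-fold (2.47 to 2.88), Foxi2 4.28-fold and Gbx2 2.00-fold lower. The otic median of −0.93 was 0.12 over members at 1 CPM or more, and Pax2 was 2.24-fold higher at 1.47 CPM. Hoxb2 was 1.76-fold and Hoxb1 7.49-fold higher, and Otx2 was 1.47-fold lower (1.41 to 1.54). Mesenchyme markers were lower in 2 of 5 cases (median −0.94).

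The largest folds up were Cxcl14 (187.5 against 2.66 CPM, 70.6-fold), Sfn (3.34-fold), Zfp503 (3.101-fold), Perp (3.09-fold) and Wnt6, and the largest down were Fabp7, Sfrp2, a secreted Wnt antagonist (4.21-fold), Cdo1 (2.76-fold), Nr2f2 (2.29-fold) and Loxl2 (2.23-fold). Of 7927 genes, 52 were at least 2-fold higher and 61 at least 2-fold lower, or 63 and 50 under median-of-ratios scaling. Stress genes were higher in 3 of 10 cases (median 0.76).

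Inside neural-like cells, all 14 measured Hox genes of groups 5 to 13 were higher at 3 than at 1.5 µM (median 7.93), 9 of 10 of groups 1 to 4 were higher (median 5.53) and all 6 rostral genes were lower (median −5.09). In mesenchyme-like cells (282 and 485) all 10 Hox genes of groups 5 to 13 were higher at 3 than at 1.5 µM (median 2.63), while all 7 measured at 1.5 against 0 µM were lower (median −2.63). In epidermis-like cells (2547 and 331) all 7 were higher at 3 than at 1.5 µM (median 5.71), with Wnt targets at a median of 2.35. In neuron-like cells (1663 and 2182) Wnt targets had a median of 0.23, with 1 of 5 past 2-fold.

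Both doses were also set against each other through the 0 µM library that they share. Over 7929 genes measured in both comparisons, 122 were at least 2-fold higher at both doses, where independent lists would share 3.61, and 93 were lower at both, where independent lists would share 3.23. Cxcl14 was the 1 gene higher at 3 µM and lower at 1.5 µM, and Fabp7 the 1 gene lower at 3 µM and higher at 1.5 µM. With both doses simulated at the 0 µM level, 0 genes passed in either comparison. That simulation holds counting error only, so it gives no bound on the overlap, and part of the excess may come from the shared library.

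The comparison of 3 with 0 µM CHIR on day 5 asked how early the axial genes differed. Rostral genes were lower at 3 µM, and Hox genes of the hindbrain and of the trunk were higher. All 7 measured rostral genes (Otx2, Six3, Six6, Hesx1, Lhx2, Lhx5, Fezf2) were at least 2-fold lower, with a median log2 of −5.90, or −7.16 with no cell filter. All 6 measured Hox genes of groups 1 to 4 (median 5.97, or 6.95 when every cell weighed alike) and all 8 of groups 5 to 13 (median 4.50, both at percentile 100) were higher. Hoxa7 stood at 169.9 against 1.45 CPM, 117-fold higher (103 to 135), and Hoxb4 at 25.8 against 0.118 CPM, 220-fold higher (137 to 377).

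Otx2 stood at 23.8 against 104.5 CPM, 4.38-fold lower (4.23 to 4.54). Six3 had 0 counts at 3 µM and 6908 at 0 µM, at least 2493-fold lower against a floor of 3 counts, and the rostral median was taken with it at that bound. Fezf2 had 1 count at 3 µM and 2454 at 0 µM, a ratio between 476 and 104980, and also entered the rostral median at the floor of 3 counts. Axin2 was 5.58-fold (5.18 to 6.01) and Sp5 31.0-fold (24.9 to 39.1) higher, while Lef1 had a ratio of 0.900 (0.864 to 0.938). Of 8 Wnt targets, 4 (Axin2, Sp5, Znrf3, Tnfrsf19) were higher and 2 (Ccnd1, Bambi) lower, with a median of 0.69. Hoxb1 was 262-fold and Hoxb2 132-fold higher. Among 4 further caudal genes, Cdx2, Egr2 (3.65-fold) and Fst (4.196-fold) were higher (median 1.79). The 4 measured Wnt ligands (Wnt4, Wnt5a, Wnt5b, Wnt6) were higher (median 2.37), Wnt6 by 65.6-fold.

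Of 5 neural markers, 4 were lower (median −2.32), with Sox1 9.05-fold and Sox21 7.84-fold lower. Pax2 was 11.4-fold lower (9.21 to 14.2), Pax8 2.27-fold higher and Gbx2 stood at 8.96 and 12.3 CPM. The anterior placode genes Six3, Hesx1 (59.9-fold) and Cryab were lower (median −5.90, or −2.65 over the 7 members at 1 CPM or more), and surface ectoderm markers were higher in 3 of 7 cases (median 0.99, Dlx5 3.63-fold). Six3 and Hesx1 also count among the rostral genes, and Hesx1 sets the median of both lists, so these medians are not separate evidence. The largest folds up were Wnt6, Hoxa7, Hoxaas3 (88.5-fold), Hoxb9 (53.6-fold) and Hoxb8 (22.4-fold). Hoxaas3 is antisense to Hox genes, so its count is uncertain. The largest down were Hand1, a trophoblast and mesoderm gene (60.6-fold), Acta2 (24.2-fold), Car4 (14.9-fold), Trp53i11 (9.95-fold) and Pou3f1 (7.88-fold).

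A Hox gene of groups 1 to 4 was seen in 29.0% of thinned cells at 3 µM (28.1 to 29.96) and 0.735% at 0 µM (0.551 to 0.9596), one of groups 5 to 13 in 46.0% (45.0 to 47.0) and 2.43% (2.08 to 2.81), and Otx2 in 6.10% (5.63 to 6.59) and 23.8% (22.8 to 24.8). Unthinned, the shares were 54.0 and 2.87%, 63.3 and 5.27%, and 19.2 and 62.1%. In pluripotent-like cells of the same libraries the shares for groups 1 to 4 were 2.81 and 0% and for groups 5 to 13 9.02 and 0.495%, at median depths of 15261 and 14747.5 UMIs. Otx2 was seen in 10.1 and 24.8% of these cells, so its share over all cells is not one of rostral cells alone. The thinning left out 102 cells at 3 µM and 182 at 0 µM. Of 7918 genes, 135 were at least 2-fold higher and 241 lower, or 183 and 187 under median-of-ratios scaling, where the median over all genes was −0.004 in place of −0.16. Stress genes were higher in 3 of 10 cases (Fosb, Junb, Egr1; median 0.83).

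The calls of both days were overlapped over 7498 genes: 39 were higher on both days and 66 lower on both, where independent lists would share 1.23 and 3.00. Trp53i11, Ppp1r14a, Irx3, Tubb3, Ebf1, Isl1 and Cdh6 were higher at 3 µM on day 8 and lower on day 5. Lefty1, Dlx5 and Dlk1 were lower on day 8 and higher on day 5. These 10 genes were named after their values were seen.

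The time course at 3 µM CHIR asked which genes differ between days 4 and 8. All measured epidermis and pan-placodal markers and 7 of 8 neuron markers were higher on day 8, as were 3 of 4 neural markers (Sox21, Hes5, Cdh2), and 5 of 7 caudal genes and 5 of 12 Wnt targets were lower. All 5 measured pan-placodal genes were higher (median log2 5.74, percentile 100, or 4.29 over members at 1 CPM or more), Eya2 at 28.5 against 0.473 CPM (60.2-fold, 44.6 to 83.3) and Irx5 by 54.7-fold. Neuron markers had a median of 6.26, which was 7.09 under median-of-ratios scaling, 7.23 with the stricter cell filter and 7.33 over members at 1 CPM or more. The 4 measured epidermis markers (Trp63, Krt5, Perp, Cdh3) were higher (median 4.11, or 5.37 when every cell weighed alike). Of 7 caudal genes, Cdx1, Cdx2, Gbx2, Nkx1-2 and Fst were lower (median −3.72), and of 12 Wnt targets 5 (Axin2, Lef1, Sp5, Notum, Dkk1) were lower and Sp8 higher (median −0.78, percentile 0). The Hox genes of groups 5 to 13, listed apart from these caudal genes, went the other way, with a median of 4.43, or 3.55 under median-of-ratios scaling.

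Axin2 stood at 50.2, 32.5, 27.3, 26.3 and 21.8 CPM on days 4, 5, 6, 7 and 8, and Sp5 at 27.1, 17.6, 10.0, 7.51 and 9.85 CPM. Gbx2 stood at 27.0, 8.96, 5.16, 2.28 and 1.49 CPM, 18.1-fold lower on day 8 than on day 4, and Nkx1-2, a gene of caudal progenitors, was 65.4-fold lower. Cdx1 was 18.2-fold, Cdx2 13.2-fold, Fst 10.6-fold, Dkk1 5.62-fold and Notum 3.19-fold lower. Otx2 stood at 23.0, 23.8, 29.8, 25.2 and 22.1 CPM. Hoxa7 and Hoxb1 were highest on day 5. Hoxa7 stood at 0.891, 169.9, 32.8, 17.8 and 11.9 CPM and Hoxb1 at 6.67, 9.07, 6.29, 3.05 and 1.08 CPM. From day 4 to day 5 all 8 measured Hox genes of groups 5 to 13 were higher (median 7.33, or 6.005 over members at 1 CPM or more), and from day 5 to day 6, 7 of 8 were lower (median −1.46). A Hox gene of groups 1 to 4 was seen in 7.81, 29.0, 17.9, 16.9 and 14.4% of thinned cells on days 4 to 8, and one of groups 5 to 13 in 1.89, 46.0, 25.8, 21.2 and 19.4%, with 214, 102, 204, 276 and 268 shallower cells left out. Without thinning the shares were 17.6, 54.0, 39.2, 38.5 and 34.5% and 5.03, 63.3, 42.5, 37.4 and 34.5%. In pluripotent-like cells, thinned, they were 1.09, 2.81, 1.86, 1.64 and 1.64% and 0.392, 9.02, 2.61, 2.68 and 2.62%, at median depths of 9442.5, 15261, 17150, 21872.5 and 23041 UMIs against 10378, 14075, 13711, 14466 and 13898 in the other cells.

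Pax8 stood at 0.352, 2.45, 6.64, 9.97 and 6.08 CPM and Pax2 at 0.055, 0.607, 0.274, 0.511 and 1.47 CPM. Sox9 was 23.5-fold, Tfap2b 40.8-fold, Snai2 28.1-fold, Sox21 7.46-fold and Cdh2 7.63-fold higher on day 8 than on day 4. Msx2 was 3.23-fold lower. The otic list had Sox9 and Jag1 higher and Gbx2 lower. Its median was 1.89 over these 3 members, 4.77 over 5 when every cell weighed alike and 4.55 over the 11 at 1 CPM or more. The largest folds up were Sst (0 counts on day 4 and 62146 on day 8, at least 12961-fold), Cxcl14 (1003-fold, 626 to 1722), Igfbp5 (514-fold), Nr2f2 (365-fold) and Neurod1 (205-fold). The largest down were Flt1 (23.7-fold), Pim2 (17.8-fold), Cdx2, Phlda2 (11.98-fold) and Fst. Of 7860 genes, 652 were at least 2-fold higher and 161 lower, or 526 and 295 under median-of-ratios scaling, where the median over all genes was −0.17 in place of 0.03. With the library titled day 10 in place of day 8 the total was 1539 in place of 813. Stress genes were higher in 4 of 10 cases (median 0.84).

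By day, 251, 52, 79 and 51 genes were at least 2-fold higher and 69, 25, 16 and 5 lower on days 5, 6, 7 and 8 than on the day before. Pan-placodal genes were higher from day 5 to 6 in 3 of 4 cases (median 1.28), and neuron markers from day 6 to 7 in 5 of 6 cases (median 2.94). Neuron-like cells made up 0, 0.0101, 0.291, 9.36 and 17.96% of cells on days 4 to 8. The 0 of 8527 cells on day 4 allows a share of up to 0.0352% by a floor of 3 counts and 0.0433% by the exact interval. Epidermis-like cells made up 0, 0.243, 15.1, 24.1 and 27.5%, and cluster 0 made up 0, 6.62, 19.1, 20.8 and 14.0%. The pluripotent-like class, which is cluster 1 alone, made up 27.3% on day 4 (26.3 to 28.2), then 22.5, 14.0, 7.18 and 6.59%. Clusters 3 and 7 also carry pluripotency markers, and they held 1.17, 8.57, 11.6, 8.46 and 7.83% and 0.786, 0.548, 0.395, 0.224 and 0.259%. They were kept out of the class by leading genes listed for another type. These were Dppa3 and Dnd1 (germ cell) in cluster 3 and Foxd3 (neural crest) in cluster 7. Otic-like cells made up 0.509, 2.36 and 3.41% on days 6, 7 and 8, in a class named mainly from the library titled day 10.

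**Figure D3:**
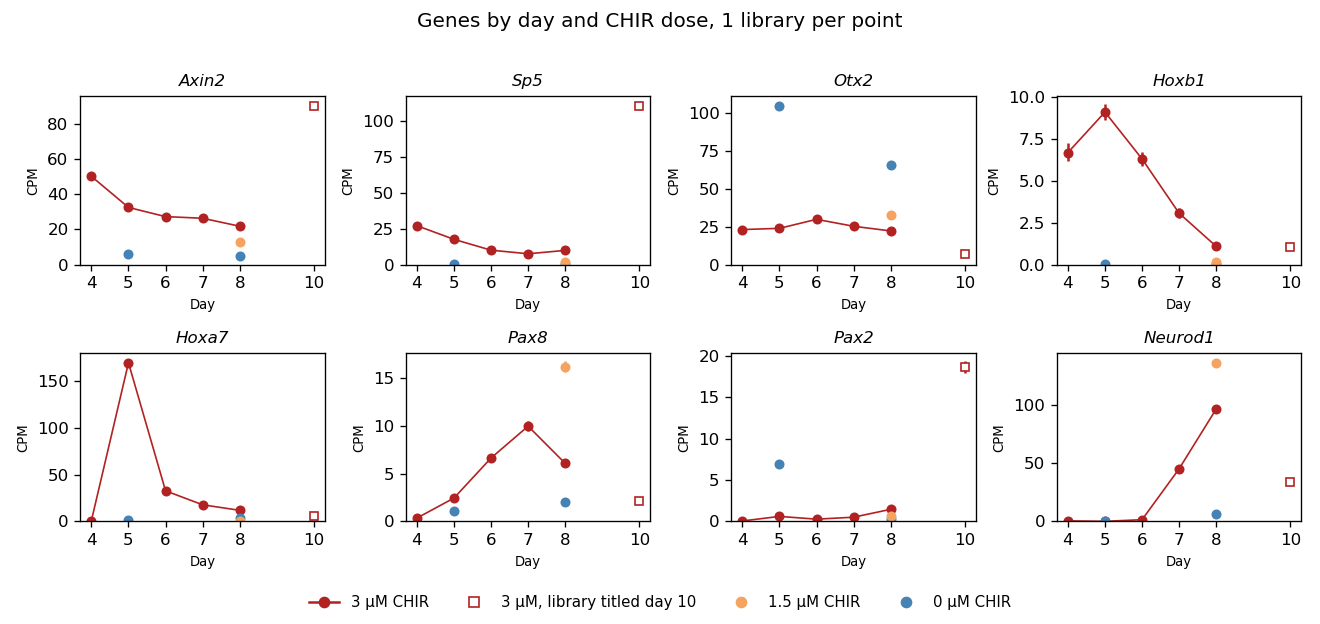
CPM of the library sum (linear axes) by day for Axin2, Sp5, Otx2, Hoxb1, Hoxa7, Pax8, Pax2 and Neurod1, with 1 point per library, bars for the exact 95% counting interval and a line through the 3 µM libraries of days 4 to 8. The open square is the library titled day 10. Hoxa7 lies at 169.9 CPM on day 5 and Axin2 at 50.2 CPM on day 4 and 21.8 CPM on day 8.

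Without CHIR, day 8 was set against day 5 to ask what time alone was accompanied by. Most mesenchyme and epidermis markers were higher on day 8, as were 4 of 8 BMP target genes, and 4 of 8 rostral genes were lower. Of 7 mesenchyme markers, 6 (Prrx1, Prrx2, Twist1, Meox1, Col1a2, Col3a1) were higher (median 2.75, percentile 100, or 3.85 over members at 1 CPM or more), Twist1 at 72.5 against 1.96 CPM (37.0-fold). Of 8 rostral genes, 4 (Six6, Hesx1, Lhx5, Fezf2) were lower (median −1.48, or −0.81 over members at 1 CPM or more), with Hesx1 8.81-fold, Fezf2 8.76-fold and Otx2 1.59-fold lower. The BMP targets Id1, Id2, Id4 and Msx1 were higher (median 0.99 over 8).

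Of 4 epidermis markers, 3 (Trp63, Krt15, Perp) were higher (median 3.40, or 1.92 over the 6 members at 1 CPM or more). Axin2 was 1.27-fold and Lef1 2.21-fold lower, and the 4 measured Wnt targets had a median of −0.41, or 0.01 over members at 1 CPM or more. Gbx2 was 8.39-fold, Pax2 20.1-fold and Cdx2 3.33-fold lower, and Pax8 was 1.87-fold higher. Of the otic list, Tbx2 (34.8-fold), Sox9 and Jag1 were higher and Gbx2 lower (median 1.40, or 3.58 over 6 members when every cell weighed alike). Wnt6 was 21.1-fold, Dlx5 8.998-fold, Dlx2 99.9-fold, Pitx1 9.17-fold, Fabp7 8.95-fold and Tfap2b 230-fold higher. The anterior placode median was −0.66, or 2.08 over members at 1 CPM or more, and the neural median was −0.38, or 0.24 when every cell weighed alike.

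The largest folds up were Barx1 (230-fold, 178 to 303), Twist1, Dlk1 (26.3-fold), Crabp1 (15.3-fold) and Nr2f2 (8.44-fold), and the largest down were Hand1 (38.5-fold), Car4 (14.7-fold), Hesx1, Pou3f1 (5.31-fold) and Nr6a1 (5.10-fold). Of 8137 genes, 301 were at least 2-fold higher and 159 lower, a total of 460 that was 691 when every cell weighed alike. Stress genes had a median of −0.02. Mesenchyme-like cells made up 0.0135% of cells on day 5 and 19.5% on day 8. Different clusters held the cells with neural markers: cluster 10 held 32.2% on day 5 and 0.849% on day 8, and cluster 19 held 0.0135 and 17.7%. Cluster 10 was kept out of the neural-like class by Six3 and Hesx1, listed as anterior placode markers although they are rostral genes as well. At least 3 neural markers were seen in 6.92% of thinned cells on day 5 (6.34 to 7.53) and 10.3% on day 8 (9.66 to 10.9), and without thinning in 25.7 and 19.4%, so no order is read from them.

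The library titled day 10 was set against day 8 at 3 µM to ask what the latest stage held. At least 2-fold higher in it were 8 of 9 otic markers, all 6 mesenchyme markers, 5 of 7 retinoic acid genes and 14 of 16 Wnt targets, and 7 of 11 pluripotency markers were lower. The higher otic markers were Pax2, Fbxo2, Hmx2, Hmx3, Gbx2, Lmx1a, Tbx2 and Sox9 (list median log2 2.06, percentile 100), with Pax2 at 18.7 against 1.47 CPM (12.8-fold, 11.1 to 14.7) and Gbx2 at 42.1 against 1.49 CPM (28.2-fold). The Wnt target median was 2.10 (percentile 100), with Sp5 11.2-fold (10.6 to 11.8), Lef1 4.89-fold and Axin2 4.13-fold higher (3.98 to 4.30). Otic-like cells made up 24.1% of its cells (23.4 to 24.9), and mesenchyme-like cells 24.1% (23.4 to 24.9), almost all of these in cluster 18, which held 23.7% of this library and may be that library rather than a cell type. The same limit holds for cluster 20, all of whose cells came from this library, as did 82.7% of all otic-like cells. Cluster 20 held 20.3% of the library, out of 26.5% in the epidermis-like class, and Dkk4, Wif1 and Fgf20 were among its leading genes.

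Fgf20 was 104-fold, Lmx1a 26.1-fold and Apcdd1 19.8-fold higher, and Pax8 was 2.80-fold, Otx2 3.29-fold, Eya2 2.28-fold and Sox21 6.19-fold lower. All 6 measured mesenchyme markers were higher (median 2.45). Of 11 pluripotency markers, 7 were lower (median −1.10, Zfp42 3.71-fold). The Hox genes of groups 5 to 13 were lower in 3 of 4 cases (median −1.24), and in 5 of 20 cases with 7 higher over members at 1 CPM or more (median −0.19). Neuron markers had a median of −0.61, and neuron-like cells made up 6.68% (6.24 to 7.15). The largest folds up were Wif1, a secreted Wnt inhibitor (385-fold, 270 to 572), Dkk4, another Wnt antagonist (299.7 against 3.503 CPM, 85.5-fold), Aldh1a3 (47.0-fold) and Apod (36.5-fold), and Sst was 8.49-fold lower. Of 8106 genes, 383 were at least 2-fold higher and 139 lower. At least 3 otic markers were seen in 7.11% of its thinned cells (6.64 to 7.60), with 646 shallower cells left out, and Pax2 in 3.85% (3.502 to 4.23). Without thinning the shares were 22.1 and 10.9%. In its epidermis-like cells, taken as background, the thinned shares were 0.639% (0.385 to 0.996) and 0.941% (0.626 to 1.36), at a median depth of 8630 UMIs against 13002 in the other cells.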

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

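The tests in this part were chosen only after the result was seen, except the tests of a whole-library shift and of clusters 18 and 20 in the library titled day 10, whose counting interval was added after its value was seen.

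The Hox genes of groups 5 to 13 were higher at 3 than at 1.5 µM on day 8. Inside cluster 8, which both libraries fill (466 and 1384 cells), the list median log2 of 3 over 1.5 µM was 7.83 (7.67 to 7.999 over 1000 redraws) with 13 of 13 members higher, which argues against cell composition as the whole source of this step and bears on no comparison with 0 µM. The 1.5 µM library held 718 UMIs of the list, 3.96% of the 18144 that its depth and the 3 µM level give. This percentage restates the depth-scaled ratio that prompted the question, so it is no separate test of depth. The 1.5 µM library was the deeper one, with 166392444 kept UMIs against 145315093 at 3 µM. Its profile correlated with a day 8 library at 0.981 and with a day 5 library at 0.907, a difference of 0.0746 that argues against a day 5 sample. Because each dose was 1 library, a dose step that acts on trunk Hox genes may lie behind this and a difference between preparations cannot be told apart from it.

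Hox genes of groups 5 to 13 were also present without CHIR on day 8, in mesenchyme-like cells. Their summed level in cluster 13 was 219.6 CPM (8228 counts) against 4.68 CPM in the other cells of that library, a ratio of 46.9 that argues against free RNA within it. Molecules carried over from the 3 µM libraries of days 5 to 8 would bring their ratio of Hoxa9 to Hoxc8, which was 0.2225 at its lowest. Cluster 13 had 21 Hoxa9 per 1915 Hoxc8 counts (0.011), a quotient of 0.0493. The 3 µM libraries of day 4 and titled day 10 were left out, so carry-over from them was not tested. No biological explanation was tested, and a difference of this 1 library stays open.

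Wnt target genes were higher in the library titled day 10 than on day 8, with a median log2 of 2.10. Its profile correlated with day 8 at 0.9475 and with day 4 at 0.8556, a difference of 0.0919 that argues against the day 4 of its characteristics. Without the cells of clusters 18 and 20, which this library alone or almost alone fills, 6553 cells remained and the median was 1.51 (1.46 to 1.57), with 10 of 13 members higher, so these clusters are not the whole source. The list median was above 0 in all 9 clusters with 100 or more cells in both libraries and enough measured targets, from 0.367 in cluster 2 (interval 0.220 to 0.712; 154 and 2260 cells) to 1.60, and this range neither shows nor excludes a shift of the whole library. Day and library preparation cannot be told apart, and no biological reading is drawn.

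For Dlk1, the log2 ratio of 3 over 0 µM was −3.24 on day 8 (15.1 against 142 CPM) and 1.34 on day 5 (13.7 against 5.41 CPM), a difference of −4.58 between opposite directions that was not tested. For Dlx5, it was −1.16 on day 8 and 1.86 on day 5, a difference of −3.02 that was likewise not tested. For Trp53i11, it was 1.90 on day 8 (69.0 against 18.5 CPM) and −3.31 on day 5 (6.35 against 63.2 CPM), a difference of 5.22, also not tested.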

How the results depend on the processing

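Taking list members at 1 CPM or more was chosen only after the result was seen. No paired analysis was possible because each condition was 1 library and the values come from no test, and for the same reason no library could be left out in turn. A move was taken as more than 1.5-fold for a count or a list median, and as a value outside the main 95% interval for a share or a single gene. By this measure 29 gene counts stayed and 26 moved, 801 list medians stayed and 45 moved, and 46 medians within a class stayed and 4 moved. Medians within a class were compared only at Leiden resolution 2 and with the axial lists among the variable genes. Another draw of cells and no doublet removal were left out. Under these 2 settings the neural-like share was 0.605% at 3 µM and 0.581% at 0 µM on day 8, respectively, so the tally does not bear on them. Of shares of cells with list genes 47 stayed and 70 moved, of class shares 59 stayed and 31 moved, and of single named genes 854 stayed and 331 moved. A named gene with 3 counts or fewer in either library was counted as having stayed, since its fold is a bound. No list median of 1 or more in size, and no named gene past the size rule, had another sign under any setting run. Of 141 list medians 32 had another sign under at least 1 setting, and the largest of these in size was 0.93. The cause of the moves given here was not tested, except that the fold and CPM minimums and the thinning depth change counts and shares by construction. Depth limits the low genes most, such as Foxi3 with 24 and 28 counts at 3 and 0 µM on day 8.

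Gene counts past the size rule are given in the order 3 against 0 µM on day 8, 1.5 against 0 µM, 3 against 1.5 µM, 3 against 0 µM on day 5, day 8 against day 4 at 3 µM, and day 8 against day 5 at 0 µM, where the main counts were 372, 390, 113, 376, 813 and 460. They were 3670, 3487, 2139, 3543, 5305 and 4119 with no CPM minimum. The counts were 86, 93, 19, 82, 174 and 115 with a minimum of 50 CPM. The counts were 1058, 883, 402, 946, 1828 and 1285 at 1.5-fold. The counts were 104, 115, 33, 128, 292 and 136 at 4-fold. When every cell weighed alike, the count of day 8 against day 5 at 0 µM was 691, of which 431 were shared with the main 460. With the library titled day 10 in place of day 8, the count against day 4 was 1539, of which 658 were shared with the main 813.

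When every cell weighed alike, the list median log2 for 3 against 0 µM on day 8 was −4.57 for rostral genes in place of −3.77, 1.42 for Hox groups 5 to 13 in place of 0.57, −1.76 for neural markers in place of −0.63 and 1.16 for neuron markers in place of 1.90. For 1.5 against 0 µM it was −0.35 for neural markers in place of 0.36, 2.11 for neuron markers in place of 2.74, −0.15 for otic markers in place of 0.60 and −2.41 for anterior placode markers in place of −1.77. For 3 against 1.5 µM it was 5.07 for Hox groups 5 to 13 in place of 4.15. For 3 against 0 µM on day 5 it was 6.95 for Hox groups 1 to 4 in place of 5.97. For day 8 against day 4 at 3 µM it was 5.37 for epidermis markers in place of 4.11 and 4.77 for otic markers in place of 1.89. For day 8 against day 5 at 0 µM it was 0.24 for neural markers in place of −0.38 and 3.58 for otic markers in place of 1.40. With list members at 1 CPM or more, the list median log2 for 3 against 0 µM on day 8 was 1.35 for Hox groups 5 to 13 in place of 0.57, 1.58 for Wnt ligands in place of 0.70, −0.60 for trophoblast markers in place of 0.55, 0.031 for otic markers in place of −0.68 and −3.62 for anterior placode markers in place of −6.46. For 1.5 against 0 µM it was −0.15 for retinoic acid response genes in place of 0.81. For 3 against 1.5 µM it was 5.26 for Hox groups 5 to 13 in place of 4.15 and 0.12 for otic markers in place of −0.93. For 3 against 0 µM on day 5 it was −0.93 for midbrain-hindbrain genes in place of 0.47, −0.99 for neuron markers in place of −2.21 and −2.65 for anterior placode markers in place of −5.90. For day 8 against day 4 at 3 µM it was 2.24 for Wnt ligands in place of 0.26, 2.69 for neural markers in place of 1.98, 7.33 for neuron markers in place of 6.26, 2.70 for neural crest markers in place of 4.81, 4.29 for pan-placodal markers in place of 5.74 and 4.55 for otic markers in place of 1.89. For day 8 against day 5 at 0 µM it was −0.81 for rostral genes in place of −1.48, 3.85 for mesenchyme markers in place of 2.75, 1.83 for neuron markers in place of 0.80, 0.16 for neural crest markers in place of 2.58, 1.92 for epidermis markers in place of 3.40 and 2.08 for anterior placode markers in place of −0.66. With no cell filter, the list median log2 for 3 against 0 µM on day 8 was −0.21 for Wnt ligands in place of 0.70 and −5.40 for anterior placode markers in place of −6.46. For 3 against 0 µM on day 5 it was −7.16 for rostral genes in place of −5.90. With the stricter cell filter, the list median log2 for 3 against 0 µM on day 8 was −0.23 for Wnt ligands in place of 0.70. For day 8 against day 4 at 3 µM it was 7.23 for neuron markers in place of 6.26. Without doublet removal, the list median log2 for 3 against 0 µM on day 8 was −5.36 for anterior placode markers in place of −6.46. Under median-of-ratios scaling, the list median log2 for day 8 against day 4 at 3 µM was 3.55 for Hox groups 5 to 13 in place of 4.43 and 7.09 for neuron markers in place of 6.26. In mesenchyme-like cells the median for Hox groups 5 to 13 was −1.89 with the axial lists among the variable genes and −1.93 at Leiden resolution 2, in place of −2.63, for 1.5 against 0 µM. For 3 against 0 µM it was 1.17 under both, in place of 0.15.

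Shares of thinned cells on day 8 are given at 3, 1.5 and 0 µM unless doses are named. Thinned to 1500 UMIs they were 2.55, 3.96 and 8.19% for Otx2, 7.71, 3.65 and 1.16% for any Hox gene of groups 1 to 4, 0.0432 and 0.0663% for both Otx2 and such a Hox gene at 3 µM and 1.5 µM, and 0.130 and 0.0884% for Pax2 at 3 µM and 1.5 µM. They were 0.853, 2.75 and 0.283% for Pax8, 9.54, 15.6 and 2.81% for the neuron list, and 0.205, 0.276 and 0.121% for the otic list at the same setting. Thinned to 5000 UMIs they were 7.78, 11.4 and 21.0% for Otx2, 20.8, 9.38 and 3.12% for any Hox gene of groups 1 to 4, 0.453, 0.693 and 0.0798% for both Otx2 and such a Hox gene, and 0.513% for Pax2 at 3 µM. They were 2.65, 7.34 and 0.797% for Pax8, 17.3 and 26.3% for the neuron list at 3 µM and 1.5 µM, and 2.42, 4.23 and 1.22% for the otic list at the same setting. With no thinning they were 17.0, 25.1 and 34.8% for Otx2, 34.5, 18.6 and 6.33% for any Hox gene of groups 1 to 4, 2.87, 3.54 and 0.839% for both Otx2 and such a Hox gene, and 0.918, 0.774 and 0.414% for Pax2. They were 5.81, 16.4 and 2.20% for Pax8, 22.6, 35.8 and 7.31% for the neuron list, and 8.91, 19.5 and 10.8% for the otic list at the same setting. With 2 list genes needed they were 19.2, 29.1 and 6.98% for the neuron list. They were 4.78, 9.67 and 5.09% for the otic list at the same setting. With 4 list genes needed they were 10.4, 17.2 and 2.93% for the neuron list. They were 0.267, 0.192 and 0.0637% for the otic list at the same setting.

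Without doublet removal, the neuron-like share of cells (day 8 unless titled day 10) was 20.1% at 3 µM in place of 17.96%, 29.1% at 1.5 µM in place of 24.1%, 5.41% at 0 µM in place of 0.829% and 7.67% in the library titled day 10 in place of 6.68%. The neural-like share was 4.76% at 3 µM in place of 5.43%, 14.0% at 1.5 µM in place of 18.5%, 0.581% at 0 µM in place of 18.3% and 0.765% in the library titled day 10 in place of 2.33%. The epidermis-like share was 3.52% at 3 µM in place of 27.5%, 2.49% at 0 µM in place of 1.80% and 27.4% in the library titled day 10 in place of 26.5%. The otic-like share was 22.1% in the library titled day 10 in place of 24.1%. With another draw of cells, the neuron-like share was 25.9% at 1.5 µM in place of 24.1% and 1.69% at 0 µM in place of 0.829%. The neural-like share was 0.605% at 3 µM in place of 5.43%, 14.5% at 1.5 µM in place of 18.5%, 17.4% at 0 µM in place of 18.3% and 0.0171% in the library titled day 10 in place of 2.33%. The epidermis-like share was 29.2% at 3 µM in place of 27.5%, 4.16% at 1.5 µM in place of 3.66% and 2.36% at 0 µM in place of 1.80%. At Leiden resolution 0.5, the neural-like share was 8.65% at 3 µM in place of 5.43% and 3.33% in the library titled day 10 in place of 2.33%. The epidermis-like share was 5.27% at 1.5 µM in place of 3.66% and 33.4% at 0 µM in place of 1.80%. With the axial lists among the variable genes, the epidermis-like share was 29.0% at 3 µM in place of 27.5% and 2.68% at 0 µM in place of 1.80%. The mesenchyme-like share was 17.4% at 0 µM in place of 19.5%. At Leiden resolution 2, the epidermis-like share was 32.6% in the library titled day 10 in place of 26.5%. The mesenchyme-like share was 17.3% at 0 µM in place of 19.5%. The otic-like share was 18.02% in the library titled day 10 in place of 24.1%.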

Other observations

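No test stands in this part, and the genes and clusters were chosen after their values were seen.

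Neuron-like cells fell into 2 clusters with different leading genes, cluster 11 (with Rgs4, Chrna3 and Nefm) and cluster 15 (with Sst, Nts and Pou4f1). Cluster 11 and cluster 15 made up 4.96 and 4.40% of cells on day 7 at 3 µM, 9.04 and 8.92% on day 8, 15.4 and 8.76% at 1.5 µM, and 0.0505 and 0.778% at 0 µM. At 0 µM on day 8 Sst stood at 19.4 CPM, against 461 CPM at 1.5 µM. In the library titled day 10 they made up 2.55 and 4.14%, and Sst stood at 50.35 CPM.

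Clusters with pluripotency markers held cells in every library. The pluripotent-like cluster 1 held 6.59% of cells at 3 µM, 4.17% at 1.5 µM and 2.75% at 0 µM on day 8, and 0.709% in the library titled day 10. Cluster 3, with Rhox5 and Dppa3 among its leading genes, held 7.83, 5.51 and 3.97% on day 8, and cluster 7, with Dnmt3l and Foxd3, held 0.259, 0.907 and 13.9%, and 25.8% at 0 µM on day 5. Pou5f1 stood at 107.9, 73.4 and 127.4 CPM at 3, 1.5 and 0 µM on day 8 and at 40.4 CPM in the library titled day 10.

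In the library titled day 10, genes of retinoic acid metabolism were higher than on day 8 at 3 µM, with 5 of 7 (Cyp26b1, Dhrs3, Aldh1a3, Rdh10, Stra6) past 2-fold and a median log2 of 2.41. Aldh1a3, which makes retinoic acid, stood at 85.1 against 1.81 CPM and Stra6, a retinol receptor, at 28.6 against 1.45 CPM. Of the BMP targets, 5 of 9 (Smad7, Msx1, Msx2, Bambi, Gata2) were higher, with a median of 1.02. Cdkn1a, a cell cycle inhibitor, stood at 807 against 146.6 CPM, while the p53 and apoptosis list had a median of −0.03 with no other member of 9 past 2-fold.

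Notch target genes were higher on day 8 than on day 4 at 3 µM in 6 of 8 cases (Hes5, Hey1, Nrarp, Lfng, Notch1, Jag1), with a median log2 of 1.53. At 3 against 1.5 µM on day 8 Hes5 was the 1 member past 2-fold, lower at 3 µM, with a list median of −0.44.

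On day 4 at 3 µM, cluster 6, with Flt1, Hand1, Cdx1 and Cdx2 among its leading genes, held 46.0% of cells and cluster 14, with Fst, Nkx1-2 and T, held 24.3%. Of all cells of these clusters, 98.3 and 85.9% came from that library. Of the unnamed clusters that held 3 or more markers of a type, cluster 16 (trophoblast markers Krt7, Ascl2 and Plac1) held 7.51 and 8.19% on days 5 and 6 at 3 µM, cluster 17 (mesenchyme markers Meox1, Foxc1 and Foxc2, led by T) held 5.10 and 7.26%, and cluster 22 (trophoblast markers Krt7, Hand1 and Plac1) held 14.7% on day 5 at 0 µM. Cluster 4 (pluripotency markers Tdgf1, Esrrb, Klf2 and Tfcp2l1, led by Stra8) held 6.62% at 3 µM, 6.49% at 1.5 µM and 0.616% at 0 µM on day 8, and 11.5% in the library titled day 10.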
